A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

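The data were 10 gPAR-CLIP libraries of S. cerevisiae strain BY4742 in 5 groups of 2 replicates, grouped by growth condition, RNA selection and gradient fraction as the labels give them. Per the labels' protocols, cells grew in synthetic defined medium with 200 µM 4-thiouracil and were irradiated 4 times at 365 nm with 150 mJ/cm2. Starved cells were rinsed and kept for 2 h in medium without glucose or nitrogen. The lysate was spun through a sucrose gradient, proteins were biotinylated, polyA RNA was taken on oligo(dT) beads where selected, and protein-bound RNA was recovered on streptavidin. The nuclease used is not given in the sources used here.

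The deposited files are cluster lists, 1 per group, with start and end coordinates, strand and a name per cluster; the descriptions of both replicates of a group name the same list, so the authors pooled replicates. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 and the build was R64. The cluster caller, its thresholds and the treatment of reads with several matches are not given in the sources used here. The score column of the deposited lists is 0 in every line, or missing for the heavy list, so the lists carry no count, coverage or significance. Names number clusters in groups, and 82.0%, 79.8%, 77.6%, 52.0% and 96% of the numbers up to the highest were present in the log-phase polyA, glucose, nitrogen, light total and heavy total lists. The precision of each value is set by the number of clusters, and every interval covers counting error only. With 1 pooled list per condition no test between conditions is possible and no p-value is given.

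Clusters were assigned on their own strand to 6475 genes of the RefSeq annotation of R64, with 5911 classed as mRNA after Ty genes were set apart. Gene bodies came before flanks and structural RNAs before mRNA, and mRNA genes were extended by 100 nt upstream and 150 nt downstream. Mitochondrial genes formed their own class. The 275 nuclear tRNA genes were merged into 41 anticodon families; the anticodon was read from the mature sequence as the loop closed by a stem that decodes the annotated amino acid, and was the same in all 23 genes where the annotation states it. The measure per gene was covered nucleotides per 100000 nt of clustered sequence in the list, and the log2 ratio was taken after adding 20 nt to each covered length. Genes with a cluster in either list entered. Ratios of cluster counts per list size have exact conditional binomial (Clopper-Pearson) 95% intervals. They are not corrected for the number of genes or for the naming of genes by their ratios. Where 1 list had 0 clusters, the lower limit of that interval is given.

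The 27 gene lists were fixed before the data were examined; 1 name in each of the lists of nitrogen catabolite repression and amino acid synthesis was not matched. Lists with at least 5 genes were described by the median log2 ratio and its percentile among 10000 random lists of the same size, matched on mean covered length in 10 bins. The measure was tested on simulated data. On simulated lists in which 200 genes were changed 4-fold up or down, the mean recovered log2 ratio in the glucose, nitrogen and total RNA settings was 1.73, 1.86 and 1.86 for raised and -1.17, -1.10 and -1.35 for lowered genes, over 5694, 5703 and 5716 genes. Of lists with no changed gene, 8%, 3% and 2% fell outside the central 95%.

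Overlap required at least 1 nt on the same strand. It was set against 100 random placements of each cluster within its own extended gene and, as a control added later, against placements with the same number of G and T. Positions in structural RNAs were set against 1000 rotations of the covered bases within each RNA. Shares have 95% Wilson intervals. To allow for the log-phase list that both starvation comparisons share, 100 sets of unchanged lists were drawn as Poisson counts from the log-phase counts.

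Genes were named by a rule fixed before the data were examined: in each comparison the 10 highest and 10 lowest log2 ratios among genes with at least 2 clusters in one list, up to 4 members with the largest absolute log2 ratio of each list described, all members of the strain, mating type, single non-coding RNA and rRNA-processing snoRNA lists that held a cluster, and every gene of the heavy list. Parts of the rule that need a score were void. Alternatives covered the gene ends, the overlap, the added length, a minimum of 3 clusters, the width of flanks, tRNA counted by gene, and either strand. Alternative gene-list settings used 2000 random lists and 1 random thinning, and overlaps 10 thinnings. Alternatives added after seeing the data were clusters of at least 10 nt, random thinning to equal list sizes, cluster counts in place of covered length, tRNA genes with a unique sequence for positions in structural RNAs, gene ends not extended for gene lists, clusters at their mean width for genes changed in both starvations and, for total against polyA RNA, the added length and the minimum of 3 clusters. Of the genes with the highest ratios, 1 is not reported here. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.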

Results

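Protein-bound stretches of yeast RNA were mapped by gPAR-CLIP, in which cells incorporate 4-thiouracil, long-wave UV crosslinks the labelled RNA to any protein it touches, and the crosslinked RNA is recovered through its biotinylated proteins. The series comprised 10 libraries of Saccharomyces cerevisiae in 5 groups of 2 replicates: polyadenylated (polyA) RNA from cells in log phase, after 2 h without glucose and after 2 h without nitrogen, all from the light part of a sucrose gradient, and total RNA of log-phase cells from the light and from the heavy part. Each group was represented by 1 list of clusters, the intervals called as protein-bound, which pooled both replicates. The lists held 61035 clusters for polyA RNA in log phase, 33345 after glucose starvation, 38936 after nitrogen starvation, 51574 for light total RNA and 115 for heavy total RNA. Median widths were 10, 11, 11, 13 and 9 nt, and the lists covered 693218, 398836, 459603, 794967 and 1579 nt. No cluster in any list lacked a T in the genomic sequence of its strand. Because no list gives values per replicate or a score per cluster, no difference between conditions had a replicate check, and the intervals given here cover counting error only. Intervals of single genes were not corrected for the choice of genes by their ratios. The list lengths stand in for depth, and read totals per library were not used here. Covered length rises with the abundance of an RNA as well as with its protein occupancy, and no unselected RNA was set against it.

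Counted with flanks of 100 nt upstream and 150 nt downstream, mRNA held most clusters of every light list. Clusters on mRNA and its flanks made up 65.2% of the log-phase polyA list (95% Wilson interval 64.8 to 65.6), 69.8% of the glucose list (69.3 to 70.3), 66.9% of the nitrogen list (66.4 to 67.3) and 80.3% of the light total RNA list (80.0 to 80.7). Without the flanks the shares were 44.7%, 43.2%, 41.9% and 64.3%. Transfer RNA held 1.04% of the clusters of light total RNA (0.959 to 1.13, from 538 clusters) against 0.218% in the log-phase polyA list (0.184 to 0.258, from 133 clusters). Clusters were counted on every tRNA gene, and most of these genes share their sequence with others, so the tRNA intervals overstate the precision. Ty retrotransposon genes held 1.18% (1.09 to 1.27) against 0.246% (0.209 to 0.288). Small nucleolar RNAs (snoRNAs), which guide the modification and processing of rRNA, held 0.729% of total RNA clusters and 0.470%, 0.972% and 0.884% of those of the log-phase, glucose and nitrogen polyA lists. RNA of mitochondrial genes held 0.773% of the log-phase polyA clusters, 1.60% after glucose starvation and 1.82% after nitrogen starvation. In clusters these were 472, 534 and 708, so part of the rise in share comes from the shorter starved lists. Clusters antisense to an annotated gene formed 10.3% of the log-phase polyA list, 4.44% of the glucose list, 6.38% of the nitrogen list and 3.70% of the light total RNA list.

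**Figure D1:**
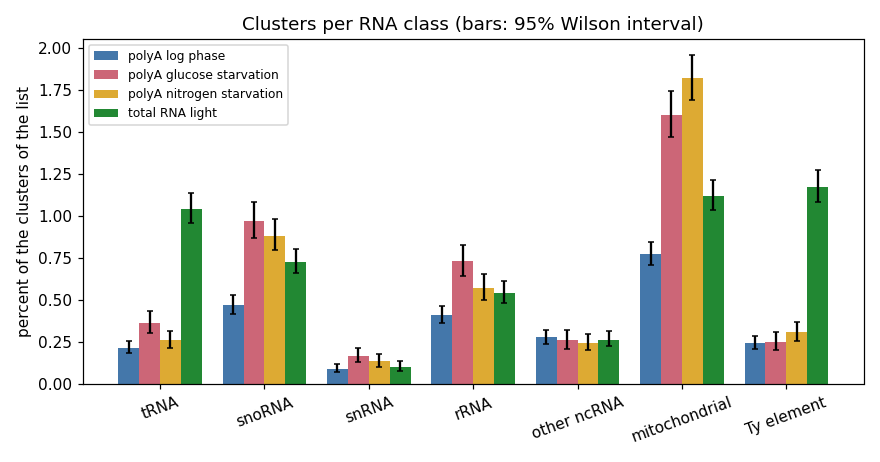
Percent of the clusters of each list (y axis) on 7 RNA classes (x axis), 1 bar per light list, with 95% Wilson intervals as error bars. Transfer RNA and Ty elements are highest in light total RNA, at 1.04% and 1.18%, and mitochondrial RNA is highest after nitrogen starvation, at 1.82%.

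Structural RNAs were the subject of the series. Each RNA was divided from its 5' end into 10 equal parts. The position of clusters was compared with the same covered bases rotated at random within each RNA. Rotation ignores where a T lies, although every cluster held one. How much of a departure from rotation comes from the spread of T along the RNA was not tested. In light total RNA, 266 of 275 nuclear tRNA genes carried a cluster in the mature part (96.7%, 95% Wilson interval 93.9 to 98.3), as did all 47 C/D box snoRNAs, all 29 H/ACA box snoRNAs and the 5 spliceosomal RNAs. Along tRNA, with genes of the same anticodon counted as 1 family, covered bases concentrated in part 3, which held 20.5% of them where rotation gave 9.85% (central 95% of rotations 7.97 to 11.9). Part 2 held 14.3% and part 10 held 13.5%, both above all 1000 rotations. Part 1 held 6.34%, part 4 held 5.91%, part 8 held 3.22% and part 9 held 5.40%, all below every rotation. In terms of the cloverleaf, a description chosen after its values were seen, the D arm held 37.9% of covered tRNA bases against 22.2% under rotation (18.9 to 25.9), and the T arm held 10.8% against 23.6% (20.2 to 27.3). The anticodon arm held 16.7% against 23.6% (20.0 to 27.3). In the log-phase polyA list, where 89 tRNA genes carried a cluster, the D arm held 14.2% against 22.7% (16.5 to 29.4) and the T arm 28.6%, within the rotations (18.4 to 30.4). After glucose and nitrogen starvation the D arm, with 16.8% (15.4 to 29.7) and 21.1% (14.3 to 31.7), lay within them. In all 4 light lists the variable region lay above the central 95% of rotations, with 13.1%, 16.1%, 12.2% and 14.5% in the log-phase, glucose, nitrogen and total lists, and the 5' strand of the acceptor stem below it. Of the 275 genes 254 share their mature sequence with another, and the treatment of reads with several matches is not given in the sources used here, so the profile is given for families and not for single genes.

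C/D box snoRNAs, whose conserved boxes sit at both ends, carried few clusters at their termini in light total RNA. Part 1 held 3.09% of covered bases against 10.4% under rotation (7.78 to 13.4) and part 10 held 5.37% against 9.73% (7.09 to 12.5). Parts 3, 4 and 8 held 16.1%, 14.9% and 13.4%, all above the central 95% of rotations, and part 5 held 5.55% against 9.73% (6.82 to 12.6). The log-phase polyA list had its highest shares in part 3, at 15.6%, and part 9, at 15.4%, and its part 1, with 6.93% (6.87 to 13.5), and part 10, with 7.44% (6.55 to 12.9), lay inside the rotations. In H/ACA snoRNAs, part 1 of light total RNA, with 13.2%, was the one value of both lists outside the central 95% of rotations (7.76 to 12.7), and in spliceosomal RNAs it was part 8 of light total RNA, with 15.8%.

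**Figure D2:**
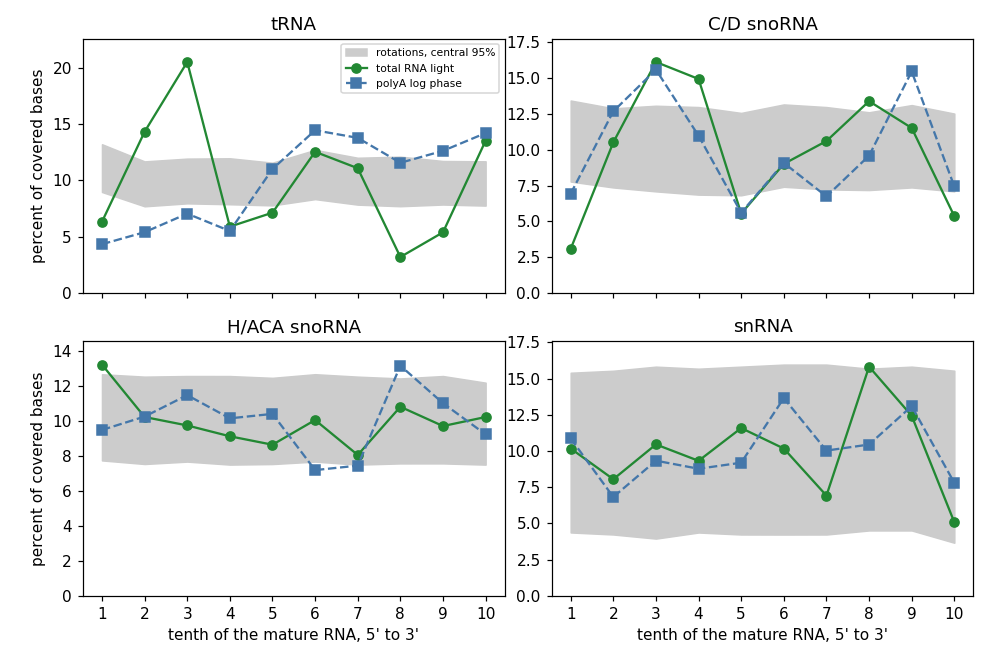
Percent of covered bases (y axis) in each of 10 equal parts of the mature RNA from the 5' to the 3' end (x axis), for 4 kinds of structural RNA. Lines show light total RNA and log-phase polyA RNA, and the grey band is the central 95% of 1000 rotations for total RNA. The tRNA line of total RNA peaks in part 3 at 20.5%, and the C/D snoRNA line of total RNA is low at both ends, at 3.09% and 5.37%.

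Among the single non-coding RNAs, the U2 RNA LSR1 (chromosome II, 680688 to 681862, R64) had 30 clusters in light total RNA and 35, 28 and 29 in the log-phase, glucose and nitrogen polyA lists. The telomerase RNA TLC1 had 25 and 21, 17 and 15, and covered length reached 35.7% of it in total RNA. The signal recognition particle RNA SCR1 had 13 and 11, 6 and 12. The RNase P RNA RPR1 had 10 and 4, 4 and 5, and the RNase MRP RNA NME1 had 9 and 7, 6 and 6. For the U1 RNA SNR19 the counts were 12 and 14, 16 and 13, for the U4 RNA SNR14 they were 4 and 3, 5 and 4, for the U5 RNA SNR7-L they were 5 and 4, 4 and 4, and for the U6 RNA SNR6 they were 3 and 1, 3 and 3. The regulatory transcript SRG1 had 6 and 4, 3 and 4, and ICR1 had 5 and 10, 1 and 1. RNA170, RUF20 and RUF21 had at most 2 clusters in any list. The U3 genes SNR17A and SNR17B, which act in 18S rRNA processing, had 11 and 7 clusters in light total RNA. The other rRNA-processing snoRNAs SNR30, SNR10, SNR190 and SNR128 had 15, 5, 5 and 2.

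Total RNA was compared with polyA RNA of the same light fraction. Their lists differed in more than the genes covered. Clusters held 16.4% G in total and 6.81% in polyA RNA, and median widths were 13 and 10 nt. The 3' flank held 13.4% of mRNA clusters in total and 24.3% in polyA RNA. Differences between genes therefore cannot be assigned to selection for a tail alone. Total RNA was richer in transfer RNA, Ty elements and mitochondrial RNA, and also in a set of metabolic and stress mRNAs. The median log2 ratio of covered length over all 5929 genes and tRNA families was -0.12, and values are given relative to it. tRNA families had a median of +1.24 (35 of 41 above the all-gene median), Ty genes +1.81 (62 of 70) and mitochondrial genes +1.00 (42 of 44), each above all 10000 random lists matched on covered length. The families Val(AAC) and Asp(GUC) had 21 and 16 clusters against 0. Counts of a family add the clusters of all its gene copies, so the same stretch may be counted on several copies. Intervals of family counts treat these clusters as independent. C/D snoRNAs at +0.19 (percentile 100) and H/ACA snoRNAs at +0.47 (percentile 99.2) were also above, while rRNA, spliceosomal RNA and other non-coding RNA lay within the random lists. C/D snoRNAs lay just inside them, at percentile 97.05, when gene ends were not extended. H/ACA snoRNAs lay inside them under 3 of 7 alternatives, down to percentile 68.2.

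Genes of trehalose and glycogen metabolism had a median of +2.03 in total against polyA RNA (17 of 20 above the all-gene median, percentile 100). The glycogen branching enzyme GLC3 had 51 clusters against 5, a ratio per list size of 12.1 (exact 95% interval 4.85 to 38.8), the glycogen synthase GSY2 56 against 6 (11.0; 4.77 to 31.4), TPS1 36 against 7 and GPH1 52 against 10. Heat shock and stress genes had a median of +1.30 (32 of 32, percentile 99.7), with HSP78 at 36 clusters against 8, HSP26 at 24 against 3, GRE1 at 15 against 3 and SSA3 at 8 against 0 (at least 2.02-fold, the lower limit of the exact interval). Amino acid synthesis genes had a median of +1.197 (65 of 75, percentile 100), with HIS4 at 61 against 9 and ARG1 at 40 against 4. Nuclear genes of the respiratory chain were above at +0.83 (32 of 36, percentile 99.4), among them ATP2 with 39 against 13, COX5B with 15 against 3, ATP14 with 11 against 3 and NDE2 with 7 against 0. They lay inside the random lists, at percentile 94.7, when only clusters of at least 10 nt were used. The mitochondrially encoded list was above at +1.19 (16 of 18, percentile 99.7), with AI2 at 34 against 6, COX3 at 16 against 2, COX2 at 18 against 7 and VAR1, which encodes a mitochondrial ribosomal protein, at 11 against 29. It lay inside them, at percentile 90.8, without extended gene ends. Ribosome biogenesis genes were less covered in total RNA, with a median of -0.75 (75 of 94 at or below the all-gene median, percentile 0.03): ENP1 had 0 clusters against 7, UTP4 0 against 6 and ERB1 1 against 8, whereas RRP5 had 12 against 2; the intervals of UTP4 and ERB1 included 1. Cytosolic ribosomal protein genes had a median of +0.27, with 108 of 138 above the all-gene median, yet below every random list matched on covered length, whose central 95% before subtraction of the all-gene median was 0.57 to 0.87 against 0.14 for these genes. The remaining lists lay within the random lists.

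Among the highest ratios were those of FAS2, INO1, TKL2, PMA2, ARO1, the Ty genes YDR034C-D and YBL100W-A, and the tRNA families Leu(UAA) and Asn(GUU). FAS2, a fatty acid synthase subunit (chromosome XVI, 108652 to 114315), had 137 clusters in total and 6 in polyA RNA, a ratio of 27.0 (12.1 to 74.9), and INO1, inositol phosphate synthase, had 46 against 3 (18.1; 5.83 to 91.2). ARO1 had 64 against 5. PMA2 had 30 against 1 and TKL2 28 against 1; both have close paralogs. The Ty genes, which are repeated in the genome, had 19 and 16 clusters against 0. The lowest were ERD1, IME1, SAP4, COS9, TAF3, RAD61, IRT1, NOC4, SLI15 and BEM4, all with 0 clusters in total RNA against 10 to 14 in polyA RNA. For ERD1 and SAP4, with 14 each, cluster counts per list size were at least 2.80-fold higher in polyA RNA.

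Of the light total RNA clusters, 32.4% (32.01 to 32.82) overlapped a log-phase polyA cluster by at least 1 nt on the same strand. For those within genes the share was 31.1%, against 16.9% when clusters were placed at random in the same genes and 23.5% when the placement also kept the number of G and T.

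The light part holds material lighter than the 40S ribosomal subunit; the heavy list, from the other part of the gradient, held clusters in ribosomal DNA alone. All 115 lay between positions 451623 and 460698 of chromosome XII, in the first of the 2 annotated rDNA repeats. Light total RNA had clusters in both, 94 in RDN25-1 and 83 in RDN25-2, so the lists may differ in how repeated sequence was treated. The 25S rRNA gene RDN25-1 held 30 clusters, the 18S gene RDN18-1 25, the 5S gene RDN5-1 4 and the 5.8S gene RDN58-1 2. The transcribed spacers of the 35S precursor held 10 (ETS1-1), 5 (ETS2-1), 3 (ITS1-1) and 1 (ITS2-1). TAR1, an open reading frame on the strand opposite 25S, held 8 with its flanks included. A further 9 were antisense to a gene and 18 intergenic. Of the 115, 80 lay on the strand of the 35S precursor. The heavy list overlapped the light total RNA list by at least 1 nt in 92 clusters, 80.0% (71.8 to 86.3). All 25 of the 18S clusters, 26 of the 30 in 25S and 2 of 5 in ETS2-1 overlapped. This overlap was not set against random placement. Light clusters covered less of ETS2-1, at 10.4%, than of the 18S and 25S genes, so these counts are not comparable. Light total RNA had 278 clusters in the same window. Heavy clusters covered 8.54% of RDN25-1 and 12.1% of RDN18-1, and light clusters 42.7% and 31.8%. RDN5-1 and ETS2-1 were covered more by the heavy list, at 49.6% and 37.9% against 35.5% and 10.4%. With 115 clusters the list is short, its calling minimum is unknown, and the many rDNA copies of the genome are represented by 2 in the reference. How the list was made is not known, so other RNAs missing from it cannot be taken as absent from the heavy part.

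**Figure D3:**
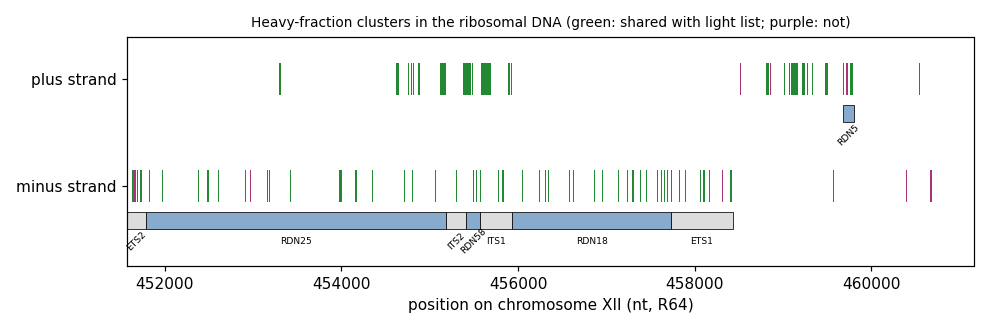
Position of the 115 heavy-fraction clusters (x axis, nt on chromosome XII) by strand (y axis), with the rRNA genes in blue and transcribed spacers in grey below the clusters. Green clusters (92) overlap a cluster of light total RNA and purple clusters do not.

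Glucose starvation was compared with log phase to see which mRNAs gained or lost protein-bound stretches. Genes encoding gluconeogenic, glycolytic and ribosome biogenesis proteins, U3 and other rRNA-processing snoRNAs, and the mitochondrial genome took a larger part of the glucose list. The median log2 ratio over 5854 genes and tRNA families was +0.26, and values are relative to it. Mitochondrially encoded genes had a median of +0.81 (17 of 18 above the all-gene median, percentile 100), with the intron reading frame BI3 at 8 clusters against 2 and OLI1, a subunit of the ATP synthase, at 7 against 6 with longer clusters. RPM1 had 2 against 1 and ATP8 1 against 0; of the 4, BI3 alone had an interval that excluded 1. Gluconeogenesis and glyoxylate cycle genes had a median of +0.65 (11 of 14, percentile 99.99), but lay inside the random lists, at percentile 95.85, with clusters of at least 10 nt alone. SIP4, a transcription factor of gluconeogenic genes, had 13 clusters against 5, a ratio per list size of 4.76 (1.59 to 17.05); CAT8 had 5 against 3, the carboxykinase gene PCK1 4 against 2 and SFC1 4 against 1, with intervals that all included 1. Glycolysis genes had a median of +0.40 (15 of 21, percentile 99.4), with pyruvate kinase CDC19 at 39 against 29 (2.46; 1.48 to 4.13), TPI1 at 20 against 14, TDH1 at 19 against 17 and TDH2 at 22 against 18. These genes lay inside the random lists with clusters of at least 10 nt alone and after random thinning, at percentile 91.9 in the lower case.

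Ribosome biogenesis genes had a median of +0.28 (68 of 94, percentile 99.99), among them RRP5 with 7 clusters against 2, RPF1 with 11 against 5, IMP4 with 4 against 3 and NOP12 with 5 against 5; the intervals of the last pair included 1. All 6 U3 and rRNA-processing snoRNAs lay above the all-gene median, at a median of +0.80 (percentile 99.9). SNR10 led at +1.21 and SNR17B at +1.15, with SNR30 at +0.85 and SNR128 at +0.75. The snoRNA class as a whole went from 0.555% of covered nt in log phase to 1.12% after glucose starvation. In nt it went from 3846 to 4469 while the list fell from 693218 to 398836 nt. The change in share thus comes largely from the shorter list. The rise in share was not particular to these 6. Proteasome genes (+0.24, 27 of 37, percentile 98.7; PRE10 6 clusters against 3, RPN10 4 against 4, RPT3 5 against 4, PRE4 3 against 4) and single non-coding RNAs (+0.41, 9 of 12, percentile 98.0) were above the random lists but inside them under 3 and 2 of 7 alternatives. Nitrogen catabolite repressed genes were below at -0.25 (25 of 39 at or below the all-gene median, percentile 1.04), and stayed below under 2 of 7 alternatives; DAL7 had 0 clusters against 5 and UGA2 1 against 6, while CAR2 had 6 against 4 and PUT1 7 against 7. The count ratios of the rRNA-processing snoRNAs, proteasome genes and nitrogen catabolite repressed genes named here all had intervals that included 1. Of 26 lists 8 lay outside the central 95% of random lists, where the nominal share gives 1.3; of simulated lists with no changed gene 8% lay outside in this setting. Hexose transporters (-0.22, percentile 7.02) lay inside, although HXT4 had 4 clusters against 22 and HXT1, whose interval included 1, 6 against 21.

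The highest single ratios in the glucose list belonged to YCR102C with 7 clusters against 0 (at least 2.64-fold), CSM4 with 5 against 0 (at least 1.68-fold), RGI2 with 4 against 0 (at least 1.21-fold), POT1, the peroxisomal thiolase of fatty acid oxidation, with 7 against 1 (12.8; 1.65 to 577), FIT3 with 10 against 2 (9.15; 1.95 to 85.9), SPG4 with 6 against 2, NDE2 with 3 against 0, the mitochondrial gene Q0255 with 6 against 1, and tRNA families Ser(GCU) and Cys(GCA) with 3 and 2 against 0. The intervals of SPG4, NDE2 and both tRNA families included 1. Genes here were picked by their ratios, so an interval that excludes 1 is no test of a change. The lowest belonged to GPR1, a plasma membrane receptor for glucose, with 1 cluster against 20 (interval of the inverse ratio 1.75 to 453), FEX2 with 0 against 11, the choline transporter HNM1 with 1 against 10, TPO3 with 1 against 15, MAK10 with 1 against 13, VRL1 with 0 against 13 (at least 1.67-fold lower), ALE2 and SLM5 with 0 against 11 each, RME2 with 0 against 9 and tRNA Leu(CAA) with 0 against 5; the intervals of HNM1 and Leu(CAA) included 1.

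**Figure D4:**
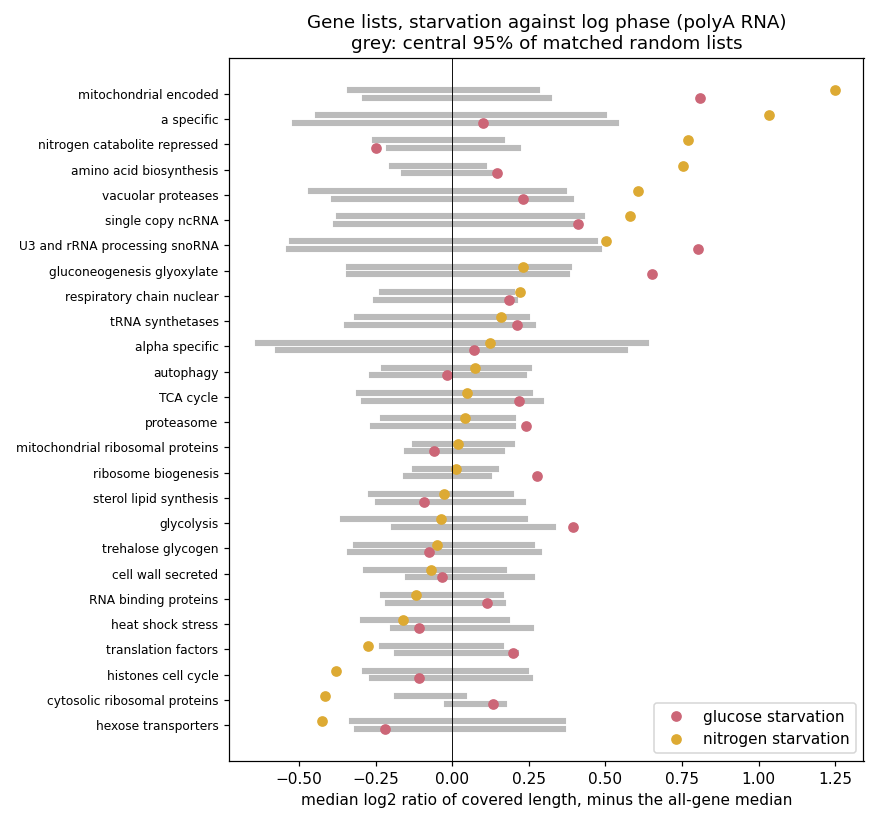
Median log2 ratio of covered length of each gene list in starved against log-phase polyA RNA, less the all-gene median (x axis), for glucose and nitrogen starvation; grey bars are the central 95% of matched random lists. Mitochondrially encoded genes lie at +0.81 and +1.25, and cytosolic ribosomal protein genes at +0.13 and -0.42.

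Nitrogen starvation was compared with log phase in the same way. Genes of nitrogen catabolite repression, which take up and break down poor nitrogen sources, and genes of amino acid synthesis took more of the nitrogen list, and cytosolic ribosomal protein genes less. The median log2 ratio over 5880 genes and tRNA families was +0.16. Relative to it, nitrogen catabolite repressed genes had a median of +0.77 (30 of 40 above, percentile 100): the allantoate permease DAL5 (chromosome X, 719666 to 721297) had 25 clusters against 3 (13.1; 3.99 to 67.6), the ammonium permease MEP2 19 against 6 (4.96; 1.91 to 15.2), DAL2 7 against 1, and the regulator DAL80 7 against 0 (at least 2.26-fold). Amino acid synthesis genes had a median of +0.75 (69 of 75, percentile 100), with ARG7 at 21 against 4 (8.23; 2.78 to 32.98), ARG1 at 23 against 4 (9.01; 3.08 to 35.9), LEU1 at 26 against 8 (5.09; 2.24 to 13.0) and GDH1 at 18 against 7 (4.03; 1.61 to 11.4). Vacuolar proteases had a median of +0.61 (6 of 10, percentile 99.7), with CPS1 at 22 against 6 (5.75; 2.26 to 17.3), LAP3 at 11 against 5, APE1 at 9 against 9 and PRB1 at 8 against 10, the last pair with intervals that included 1. Autophagy genes as a list lay within the random lists (+0.07, percentile 71.4).

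Mitochondrially encoded genes were again higher, at +1.25 (18 of 18, percentile 100), with BI3 at 13 clusters against 2, BI4 at 15 against 5, COB at 12 against 6 and ATP8 at 3 against 0. Nuclear respiratory chain genes had a median of +0.22 (24 of 36, percentile 98.5; COX9 and COX5B 5 against 3 each, NDE2 1 against 0, COR1 7 against 16). Single non-coding RNAs had +0.58 (11 of 13, percentile 99.7), rRNA-processing snoRNAs +0.50 (5 of 6, percentile 98.3; SNR10 9 against 5, SNR190 7 against 6, SNR30 15 against 13, SNR17B 4 against 6) and a-specific genes +1.03 (7 of 8, percentile 100), the last from few clusters: AGA2 4 against 0, MFA1 4 against 3, MFA2 5 against 2 and ASG7 1 against 0, flanks included. The 138 cytosolic ribosomal protein genes had a median of -0.42 (117 at or below the all-gene median, percentile 0), with RPS2 at 5 clusters against 18, RPL5 at 6 against 20, RPL12A at 3 against 14 and RPL34B at 4 against 10. Hexose transporters had -0.43 (12 of 16 at or below, percentile 0.51), with HXT4 at 3 against 22 (inverse ratio 4.68; 1.41 to 24.4) and HXT6 at 7 against 24, SNF3 at 0 against 8 and RGT2 at 9 against 8. Histone and cell cycle genes had -0.38 (21 of 26, percentile 0.28; CLN2 3 against 13, CLN1 1 against 8, HHT1 6 against 12, CDC20 0 against 5), and translation factors -0.27 (31 of 44, percentile 0.89; GCD1 1 against 7, TIF4632 1 against 6, SUI1 3 against 5, CAM1 8 against 7). Translation factors were inside the random lists under 2 of 7 alternatives, up to percentile 44.1, and rRNA-processing snoRNAs under 3, down to percentile 94.1. The snoRNA class as a whole also rose in share, from 0.555% of covered nt in log phase to 1.03% after nitrogen starvation. In nt it went from 3846 to 4754 while the list fell from 693218 to 459603 nt. Respiratory chain, single non-coding RNA, vacuolar protease and histone and cell cycle genes were inside under 1 each, at percentiles 89.8, 95.45, 97.3 and 2.55. Among the genes named in this paragraph the intervals of BI3, BI4, COB, AGA2, HXT4 and SNF3 excluded 1, and all others included it. In all, 12 of 26 lists lay outside the central 95%, where the nominal share gives 1.3; of simulated lists with no changed gene 3% lay outside in this setting.

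Other high ratios in the nitrogen list were those of the sulfate permease SUL1 with 12 clusters against 0 (at least 4.36-fold), SNZ1 with 9 against 1 (14.1; 1.95 to 618), YHI9 with 17 against 3 (8.88; 2.57 to 47.3), Q0255 with 14 against 1, and the tRNA families Asn(GUU) with 11 against 1 and Cys(GCA) with 7 against 0. The lowest were the kinase YPK2 with 0 against 16 (at least 2.46-fold lower), FCY21 and HOB2 with 0 against 10 each (at least 1.43-fold lower), ALD6, an acetaldehyde dehydrogenase, with 3 against 22 (inverse ratio 4.68; 1.41 to 24.4), the amino acid permeases TAT1 with 1 against 13 and BAP3 with 1 against 11, EBS1 and KAP95 with 1 against 13 each, HXT4, and tRNA Leu(CAA) with 1 against 5, whose interval included 1. The library codes in the labels carry one prefix for all log-phase libraries and another for all starved ones. Shifts that both starved lists share, such as that of mitochondrially encoded genes, therefore cannot be told apart from a preparation batch. The total RNA comparison has the same log-phase polyA list as reference, and mitochondrially encoded genes were above there too, at +1.19. Amino acid synthesis genes were above in the nitrogen and total comparisons, at +0.75 and +1.197. After glucose starvation they were at +0.15, within the random lists. Low values in the shared reference list would raise each comparison, and this was not tested. Nitrogen catabolite repressed genes, at +0.77 after nitrogen and -0.25 after glucose starvation, and cytosolic ribosomal protein genes, at -0.42 and +0.13, did not move alike in both.

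Most clusters of each starved list met a cluster of the longer log-phase list. Of the glucose clusters, 73.8% (73.3 to 74.2) overlapped a log-phase cluster by at least 1 nt on the same strand, and of the nitrogen clusters 70.2% (69.8 to 70.7). In the other direction 40.4% and 45.1% of log-phase clusters were met, since that list is longer. Of the glucose clusters 63.3% (62.8 to 63.8) overlapped a nitrogen cluster. Within genes the shares were 74.3%, 73.1% and 64.5%, against means of 16.8%, 15.6% and 12.4% over 100 random placements in the same genes and 38.7%, 38.8% and 31.1% when the placement also kept the number of G and T. Overlap fell to 51.8%, 49.8% and 45.9% when at least 50% of each cluster had to be shared. With the lists of each pair thinned to equal numbers of clusters it was 40.7%, 45.2% and 54.3%. Thinning deletes clusters of the longer list at random, so overlap falls most where the lists differ most in length. The changed order of the overlaps therefore does not tell which lists are most alike.

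Genes that departed from log phase in one starvation tended to depart in the other, and both comparisons share the log-phase list. Across 5906 genes and tRNA families, which are not independent replicates, the log2 ratios of cluster counts had a Pearson r of 0.502, where unchanged lists simulated from the log-phase counts gave a mean of 0.455 and a maximum of 0.484 over 100 simulations. The covariance was 0.261, below the simulated mean of 0.336. With a log2 ratio of covered length at least 1 above the all-gene median, 249 genes were higher after glucose and 271 after nitrogen starvation, 67 in both, where independent lists would share 11.6. At least 1 below it were 368 and 290 genes, 96 in both, against 18.3. On the measure of the simulation, in which every cluster has the mean width, 206 and 211 genes were higher, 70 in both, and 333 and 272 lower, 89 in both. Unchanged simulated lists had means of 460 and 421 higher genes, 195 in both, and 431 and 390 lower genes, 79.3 in both. They thus hold more changed genes than the observed lists; the simulation adds noise to counts that already hold it. Their overlap is no matched chance value, and the pooled log-phase list cannot be split, so how much of the relation comes from the shared list was not resolved.

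Within mRNA, a larger share of clusters lay toward the 3' end in the starved lists. The 3' flank, up to 150 nt beyond the stop codon, held 24.3% of mRNA clusters in log-phase polyA RNA (23.9 to 24.7), 30.6% after glucose starvation (30.0 to 31.2), 30.4% after nitrogen starvation (29.85 to 30.97) and 13.4% in light total RNA (13.1 to 13.7). Coding sequence held 66.0%, 59.4%, 59.8% and 77.1%, and the 5' flank 8.15%, 8.69%, 8.16% and 8.20%. Annotated introns held 1.51%, 1.32%, 1.61% and 1.27%. With coding sequences divided into 10 equal parts, part 10 held 10.5% of clusters in log phase, 12.6% and 12.5% in the starved lists, and 9.96% in total RNA, whereas part 1 held 13.2% in total RNA and 9.35%, 10.3% and 8.68% in the polyA lists. These intervals treat clusters as independent.

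The strain label gives BY4742 with deletions in HIS3, LEU2, LYS2 and URA3, and calls the mating type a. No cluster lay in the reading frames of LEU2, LYS2 or URA3 in any list, on either strand. Each of the 3 polyA lists had 1 cluster in the flanks of LEU2. HIS3 (chromosome XV, 721946 to 722608) held 10 clusters in light total RNA and 1 in the nitrogen list. The 10 left a gap of 305 nt, from base 285 to base 589 of the 663-nt frame, which spans both HindIII sites of the gene, at bases 305 and 495; 8 clusters lay before it and 2 after. The nitrogen cluster covered bases 596 to 624. All 5 genes expressed in alpha cells held clusters in each light list: SAG1 12, 11, 10 and 16 in the log-phase, glucose, nitrogen and total lists, the alpha-factor genes MF(ALPHA)1 10, 4, 8 and 14 and MF(ALPHA)2 4, 4, 7 and 1, the a-factor receptor STE3 11, 2, 2 and 13, and AFB1 6, 7, 5 and 3. Of genes expressed in a cells, MFA1, MFA2, AGA2, ASG7 and BAR1 held 0 or 1 in their reading frames in every list. STE2 held 7, 0, 7 and 4, STE6 7, 1, 5 and 4, and AXL1 16, 6, 8 and 10. Clusters in all 5 alpha-cell genes are not expected of a cells, so the mating-type label is in doubt, and with it what the +1.03 of the a-specific list after nitrogen starvation means.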

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

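The alternatives with clusters of at least 10 nt, random thinning, cluster counts, unique tRNA genes, clusters at their mean width, for gene lists unextended gene ends and, for total against polyA RNA, added length and minimum cluster number were chosen after seeing the data. No paired analysis was possible because each list pools both replicates, and for the same reason no replicate could be left out. The alternatives that need a score (top-scored clusters, summed score, score-weighted bases) were not run, since no score is given. The cause of each movement below was not tested unless stated.

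Without extended gene ends, mRNA held 44.7%, 43.2%, 41.9% and 64.3% of clusters in the log-phase, glucose, nitrogen and total lists, because flank clusters become intergenic. With clusters of at least 10 nt mRNA held 67.1%, 71.0%, 68.0% and 81.1%, and structural and non-coding RNA 1.87%, 3.01% and 2.47% in the polyA lists. The overlaps of glucose with log phase, nitrogen with log phase and glucose with nitrogen were 51.8%, 49.8% and 45.9% at 50% of each cluster, 40.7%, 45.2% and 54.3% after thinning, and 58.2%, 54.3% and 52.3% with clusters of at least 10 nt. The heavy overlap was 69.6% at 50% of the heavy cluster. Part 3 of 10 of tRNA held 16.98% with every gene counted on its own and 20.9% over the 21 genes with a unique sequence. The 3' flank held 16.7%, 22.4%, 21.97% and 9.33% of mRNA clusters with flanks of 50 and 75 nt, and 28.7%, 33.7%, 34.4% and 15.9% with 200 and 300 nt, in the order log phase, glucose, nitrogen and total; both starved lists stayed above log phase and total RNA below it in both.

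The number of glucose lists outside the random range was 5 with clusters of at least 10 nt, against 8; the other counts of lists stayed within 1.5 times. Of 32 lists outside the range in the 3 comparisons, 17 lay past it on the same side in all 7 alternatives (3 of 8 for glucose, 6 of 12 for nitrogen, 8 of 12 for total RNA). In 28 further settings a list kept its direction but came inside the range, and none reversed. The number of clusters per gene limits the single-gene ratios.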

Other observations

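The tests on tRNA flanks, snoRNA boxes, Puf3 sites, G content in clusters, and the heat shock list alone were chosen after the result was seen; those on gene length, G content of the 3 gene lists and composition-matched overlap were fixed before their results.

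Flanks and introns of tRNA genes also carried clusters. In light total RNA, 129 of 275 tRNA genes (46.9%, 95% Wilson interval 41.1 to 52.8) had a cluster over at least 3 nt of the 30 nt past the 3' end, against 55 (20.0%, 15.7 to 25.1) for the 30 nt before the 5' end, and 46 of the 60 intron-containing tRNA genes had one in the intron (76.7%, 64.6 to 85.6). In the log-phase polyA list the trailer was covered in 97 genes and the leader in 16, while the mature part was covered in 89. After glucose starvation these counts were 51, 1 and 73, and after nitrogen starvation 55, 10 and 69. Introns were covered in 24 of 60 genes in log phase, 16 after glucose and 7 after nitrogen starvation. Whether these clusters lie on tRNA precursors or on neighbouring or read-through transcripts was not tested.

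The conserved boxes of C/D snoRNAs, which bind the core proteins of the particle, were less often under clusters than under rotated ones. In light total RNA 3 of 38 D boxes (7.89%) and 8 of 38 C boxes (21.1%) overlapped a cluster, where rotation of the covered bases gave 45.9% (31.6 to 60.5) and 52.6% (36.8 to 68.4). For the ACA box of H/ACA snoRNAs the count was 6 of 18 (33.3%), within the rotations (22.2 to 66.7). The C and D boxes sit at both ends of the RNA, where light total RNA already held few covered bases. Their counts are therefore not independent of that low coverage. Rotation also ignores where a T lies, although every cluster held one. No explanation was tested.

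Clusters of starved cells met log-phase clusters more often than chance placement. Base composition alone did not account for this. Placement within the same gene at sites with equal numbers of G and T gave 38.7% for glucose and 38.8% for nitrogen. The observed shares of clusters within genes were 74.3% and 73.1%, and the smaller of the differences was 34.26 percentage points. Exact sequence preference of crosslinking and mapping remain open.

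Clusters of polyA RNA were poor in G, at 6.81%, 6.88% and 5.63% of bases in the log-phase, glucose and nitrogen lists against 16.4% in light total RNA. Different transcripts do not account for it, since within coding sequences of the 4935 mRNA genes with clusters in both log-phase light lists the total list exceeded the polyA list by 9.78 percentage points (18.3% against 8.49%; coding sequence 20.5%). Cutting of unpaired RNA at G in the polyA libraries is a candidate explanation. G was 2.41 times as frequent directly before a log-phase polyA cluster as 3 bases upstream (20.6% against 8.56%), and log-phase polyA clusters on tRNA, rRNA and snoRNA held 21.9%, 26.2% and 14.9% G, against 26.9%, 28.4% and 16.98% in light total RNA. The requirement that G before a cluster also lie above 1.5 times its share of coding sequence was added after these values were seen, and was not met. The share of 20.6% is close to that of coding sequence, and total RNA had a ratio of 1.49, so nuclease cutting and the selection step cannot be told apart here.

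Trehalose, heat shock and amino acid synthesis genes were over-represented in total against polyA RNA. The log2 ratio rose with the G content of coding sequence (r = 0.214 across 5637 genes, which are not independent). After that trend was removed the median log2 ratio of trehalose genes went from 1.91 to 1.99 and that of amino acid synthesis genes from 1.07 to 1.16. The trend with coding length was weak (r = 0.0415), and after its removal the medians of the trehalose, heat shock and amino acid lists were 1.81, 1.45 and 1.26. The median percentile of the 3 lists was 100 after either step; it was at this upper limit before, so it could fall but not rise. These values argue against length as the whole cause for the 3 lists, and against G content for trehalose and amino acid synthesis genes. For heat shock genes alone the percentile went from 99.7 to 96.6 after the G trend was removed, with a median log2 ratio of 1.17 before and 1.16 after, so a part played by G content stays open there. A difference in polyadenylation or in growth of the cultures was not tested.

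Sites for the 3' UTR binding protein Puf3 offered a test of a known RNA-binding protein. A broader form of the site was looked at first; the value here is for TGTAAATA within 200 nt past stop codons, set against 200 scrambled sites of the same bases. In light total RNA 50 of 260 sites carried a cluster (19.2%), percentile 100 of the scrambled sites, and after nitrogen starvation 49 (18.8%), percentile 96. In log phase 52 (20%) gave percentile 90 and after glucose starvation 37 (14.2%) gave percentile 83.5. The hypothesis that Puf3 sites are bound beyond their AU-rich composition is in line with the total RNA list and, narrowly, the nitrogen list; composition could account for the log-phase and glucose values. The lists were judged one by one only after the values were seen.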
